A study of Rattus norvegicus with 8 samples.

How the data were processed

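Total RNA of pooled pineal glands from Sprague-Dawley rats was sequenced at 4 ages and 2 times of day, with 1 library for each age and time (8 libraries). Per the submitters' notes, 10 µg of total RNA was enriched for polyadenylated RNA and primed with random primers. Libraries had 16 cycles of PCR and were read as paired ends of 101 bases, 4 libraries to a lane. The lane of each library is not given, so lanes could not be tested as batches. Per the labels, the authors used TopHat 1.3.1 and Cufflinks 1.2.0 with genome build rn4 and deposited the values as FPKM, 1 for each RefSeq transcript. Filters and any scaling between libraries beyond FPKM are not stated. The deposited FPKM of the 8 libraries sum to different totals, and the values given per sample were identical to those of the series for all 8 libraries.

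The deposited values cover 16932 transcripts of 16462 gene symbols, of which 2960 were at 0 in every library. For 343 symbols there is more than 1 transcript (813 transcripts, up to 11 for a symbol), and each was kept as deposited. A date stands in place of the symbol for 24 transcripts, and these were not named. Of 33 housekeeping genes 32 were found, and Gapdh, Ppia, Rpl13a and Rps18 lay under 2 FPKM in every library (highest values 0.524, 1.32, 1.86 and 0.579 FPKM). No correction was made for genes with near-identical copies. Counts and read totals were not used here. The relative depth was taken from the smallest step between FPKM values of olfactory receptor transcripts spanning at most 1100 bp, at which 1 fragment is added. It limits low values most in the P20 mid-day library. With no counts, no counting intervals are given.

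Values were analysed as log2(FPKM + 1), which understates changes of transcripts near or under 1 FPKM, with no further scaling. The 9960 transcripts with at least 1 FPKM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). The first fit had age and time of day as terms (3 residual degrees of freedom, prior 4.816) and gave the age F test, P40 against E21, the successive ages and mid-night against mid-day over the 4 ages. The second had age, 1 night effect for E21 and P5 and 1 for P20 and P40 (2 residual degrees of freedom), and gave these effects and their difference. At a single age there is 1 library for each time, so transcripts at least 2-fold apart were counted without a test. No paired analysis within an age was possible because each age and time has 1 pooled library; age served as the block.

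Lists of genes were tested with camera at an inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, with each gene represented by its transcript of highest mean FPKM. They covered melatonin synthesis, phototransduction, pineal transcription factors, genes known as night-higher in the adult gland, the circadian clock, immediate early genes, adrenergic and cyclic AMP signalling, cell cycle, immature neurons, oncofetal and imprinted genes, cholesterol synthesis, oxidative phosphorylation, thyroid hormone and antigen presentation. Markers of other cell types covered astrocytes, microglia, endothelium, smooth muscle, erythroid cells, oligodendrocytes, Schwann cells, choroid plexus, habenula and other brain neurons, skeletal muscle, mast cells, and matrix and fibroblasts. Lists with fewer than 3 genes tested are given as values. Some genes are in more than 1 list, such as Ttr in the thyroid and choroid plexus lists. The night-higher list shares Aanat and Mat2a with melatonin synthesis, Dusp1 and Nr4a1 with immediate early genes, and Per1 with the clock. It also shares Crem, Pde4b and Pde10a with adrenergic and cyclic AMP signalling and Dio2 with thyroid hormone. Fcer1a, which the gland expresses, is among mast cell markers. For a single age, a list median was placed among 10000 random lists matched on mean expression, as a description.

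The groups, limma and list tests, lists, most alternatives and the rule for named genes were set before the data were examined. The alternatives without both P5 libraries and without transcripts spanning under 2 kb of the genome were added after. So were the tests of explanations, most of them before their own values were computed. Named were the 10 largest changes each way past the test for P40 against E21 and for night at P20 and P40, and the 4 largest each way for successive ages, each with at least 5 FPKM in 2 libraries. For single ages these were the 6 highest and 4 lowest differences with at least 10 FPKM in the higher library, and for the difference of night effects the 10 with the lowest p. From each list 2 to 4 genes are quoted, those of highest mean FPKM past the test, and members of the melatonin and night-higher lists. Gnat1, Lhx9, Pax6, Fos and, for P40 against P20, Cd74 and Irf7 were quoted in addition, chosen after their values were seen.

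Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization, median centring, eBayes without trend or robust, a 2-fold minimum, other codings of age and time, 1.5-fold and 3-fold limits, transcripts summed per symbol, and each library and each age left out in turn. Where an age then keeps 1 library, that library is assumed to vary like the others in contrasts of ages. For night effects the age term absorbs it, so leaving out either library of an age takes that age out of the night effect. The method was tested on simulated data of the same design with 50 transcripts changed at each of 4 sizes. These were drawn from transcripts with a mean log2(FPKM + 1) above log2 of 5. Noise was independent and normal with the spread left by the second fit, and no other transcript changed with age or time. In the data more transcripts changed, and night differences that depend on age add to the error of the first fit. Recovery and false calls in the data may therefore differ. For P40 against E21, 56% were recovered at a log2 change of 1 and 88% at 2, for night at P20 and P40 36% and 76%, and for the difference of night effects 2% and 52%. Of the calls in these simulations, 5.62%, 1.92% and 1.02% were false. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the tables and figures. No genome sequence was used, and sequence composition was not tested.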

Results

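Pineal glands of Sprague-Dawley rats were sampled at 4 ages, embryonic day 21 (E21) and postnatal days 5, 20 and 40 (P5, P20 and P40), to follow the transcriptome through development and to find transcripts that differ between day and night at each age. At every age 1 library was made from glands taken at mid-day (zeitgeber time 7) and 1 from glands taken at mid-night (zeitgeber time 19), in a cycle of 14 h of light and 10 h of dark. Each library was a pool: 13 animals at mid-day and 15 at mid-night at E21, 17 and 19 at P5, 13 and 10 at P20, and 3 and 3 at P40. Between 8598 transcripts (P20 mid-night) and 9533 transcripts (P5 mid-night) reached 1 FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library). Read totals are not part of the FPKM values. The smallest steps between FPKM values placed the depth of each library, relative to the deepest one (P40 mid-night), at 0.53 and 0.69 for E21 mid-day and mid-night, 0.91 and 0.57 for P5, 0.41 and 0.59 for P20, and 0.82 for P40 mid-day. No age and time was sampled more than once. The p-values therefore measure only the spread between these pooled libraries, which for change with age includes night differences that depend on age. Differences at a single age carry no p-value.

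Age was the main axis of the data. The first principal component held 63.5% of the variance and placed the libraries from E21 (-63.2 and -57.24) through P5 (-7.1 and -11.31) to P20 and P40 (25.4 to 44.32). The third, with 10.9%, set the mid-day libraries of P20 and P40 (21.43 and 19.62) apart from their mid-night libraries (-25.28 and -20.04). Across transcripts, the correlation of 2 libraries ran from 0.732, for E21 mid-day and P40 mid-night, to 0.973, for the 2 libraries of P5. Of 9960 transcripts tested with limma, 3629 changed with age at an adjusted p under 0.05, and 2626 of them also spanned at least 2-fold between ages. Without the E21 mid-day library the count was 2369.

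The comparison of P40 with E21 addresses what the gland gains and loses between late gestation and young adulthood. Of the genes tested, 4 of 8 for melatonin synthesis and 23 of 32 for phototransduction rose. Asmt, which encodes the last enzyme of melatonin synthesis, went from 0.810 ± 0.535 to 165 ± 60.0 FPKM (mean ± SD, n = 2 libraries per age). Tph1, which encodes the enzyme that hydroxylates tryptophan, went from 350 ± 27.5 to 2641 ± 163 FPKM. All 19 genes of antigen presentation tested rose, among them Cd74, the invariant chain of class II molecules, from 0.589 ± 0.157 to 19.9 ± 1.10 FPKM. Of the cell-cycle genes 26 of 27 fell, and of the matrix genes 18 of 19. Top2a, a topoisomerase of dividing cells, went from 34.2 ± 6.96 to 0.501 ± 0.110 FPKM, and Postn, a matrix protein, from 170 ± 9.95 to 6.99 ± 1.07 FPKM. H19, an imprinted fetal RNA, fell from 255 ± 31.1 to 0.410 ± 0.0681 FPKM.

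**Figure D1:**
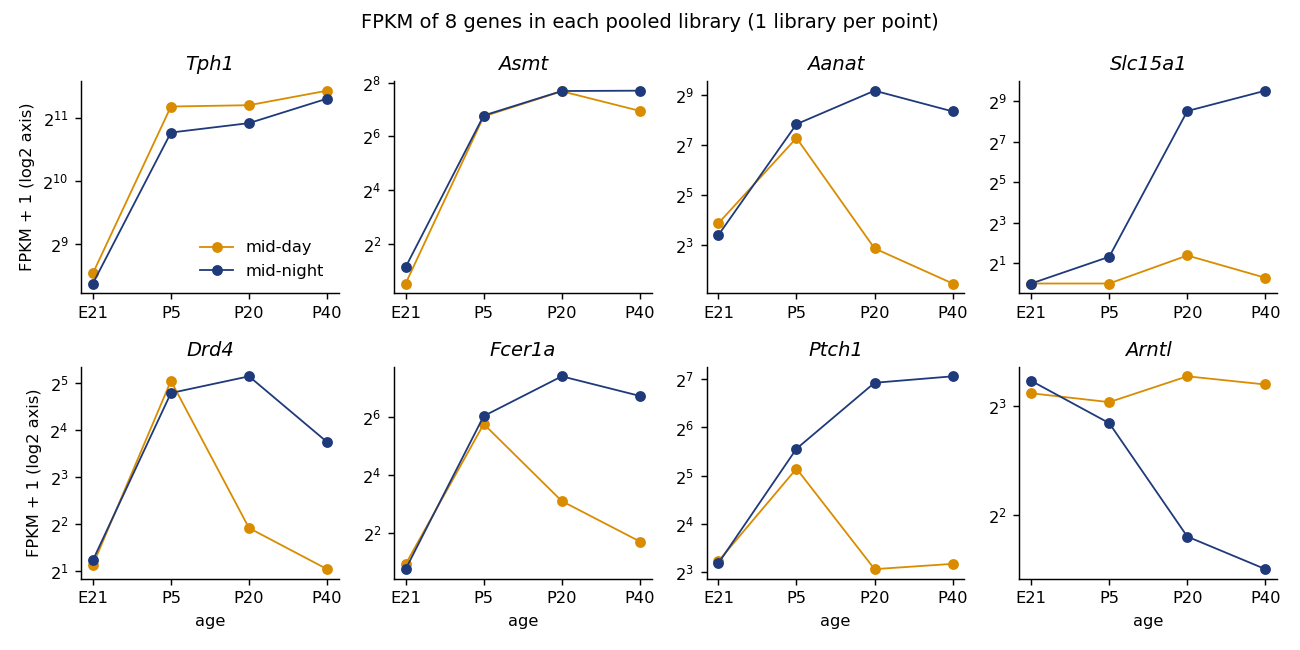
FPKM + 1 on a log2 axis for 8 genes at the 4 ages, each point 1 pooled library, orange for mid-day and blue for mid-night. Tph1 and Asmt were higher from P5 on in both libraries, whereas Aanat, Slc15a1, Drd4, Fcer1a and Ptch1 separated by time of day at P20 and P40, when Arntl was lower at mid-night.

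Of 8 genes of melatonin synthesis tested, 4 rose between E21 and P40, both over all genes and adjusted over the list alone. Asmt rose by a log2 change of 6.50 ± 0.24 (SE; adjusted p = 1.1e-05), Gch1 by 3.62 ± 0.27, Tph1 by 2.91 ± 0.42 and Ddc by 2.84 ± 0.30. The others did not pass. Aanat, the acetyltransferase that sets the rhythm of melatonin, was at 1.27 ± 1.68 (adjusted p = 0.566) and Mat2a at 0.704 (adjusted p = 0.341). A night difference that depends on age adds to the error of this fit, so this does not show that both were unchanged. The list median was 2.05 (camera, adjusted p = 0.00286; adjusted p = 0.444 with an estimated correlation). Of 32 phototransduction genes, 23 rose (23 adjusted over the list alone) and 1 fell (2 over the list alone). Their median was 2.04 (camera, adjusted p = 1.78e-12; adjusted p = 0.360 with an estimated correlation). Gngt2, a subunit of the cone transducin, rose by 4.46 ± 0.30 to 1292 ± 349 FPKM, the visual cycle gene Rbp3 by 1.46 ± 0.29 and the disc protein gene Prph2 by 2.53 ± 0.40. Gnat1, the rod transducin alpha subunit, fell by 0.73. All 19 antigen presentation and interferon genes rose (19 adjusted over the list alone), with a median of 1.79 (camera, adjusted p = 4.55e-13; adjusted p = 0.360 with an estimated correlation). Examples were Cd74 (3.72 ± 0.27), the interferon regulator Irf7 (3.73 ± 0.20) and B2m, the light chain of class I molecules (1.57 ± 0.23).

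Of 27 cell-cycle genes 26 fell (26 adjusted over the list alone), with a median of -2.72 (camera, adjusted p = 1.64e-13; adjusted p = 0.368 with an estimated correlation). Top2a changed by -4.54 ± 0.22, the mitotic kinase gene Cdk1 by -4.10 ± 0.24 and the replication clamp gene Pcna by -1.38 ± 0.37. Of 16 immature neuron genes 13 fell (13 over the list alone), median -1.63 (camera, adjusted p = 1.25e-05; adjusted p = 0.360 with an estimated correlation). Among them were the tubulin gene Tubb2b (-4.74 ± 0.17), Marcksl1 (-2.93 ± 0.28) and Nnat. The 2 transcripts of Nnat changed by -2.42 and -5.47. Of 8 oncofetal and imprinted genes 6 fell (6 over the list alone), median -1.92 (camera, adjusted p = 0.000956; adjusted p = 0.436 with an estimated correlation). H19 changed by -7.50 ± 0.27, the fetal growth factor Igf2 by -4.11 ± 0.27 and the cell-cycle inhibitor gene Cdkn1c by -3.96 ± 0.37. Of 19 extracellular matrix and fibroblast genes 18 fell (18 over the list alone), median -1.86 (camera, adjusted p = 4.28e-07; adjusted p = 0.444 with an estimated correlation). The collagen genes Col1a1 (-3.54 ± 0.31) and Col3a1 (-2.69 ± 0.28) were among them. Endothelial markers fell in 8 of 9 cases (8 over the list alone), among them Emcn and Cdh5 (camera, adjusted p = 0.00224; adjusted p = 0.478 with an estimated correlation). Erythroid genes fell in 4 of 7 cases (6 over the list alone), among them the globin gene Hba-a2 by -3.70 ± 0.52 (camera, adjusted p = 0.0461; adjusted p = 0.550 with an estimated correlation).

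Genes of other groups moved in smaller numbers. Of 31 oxidative phosphorylation genes 12 rose and 3 fell (13 and 3 adjusted over the list alone), with Cox6c up by 2.96 ± 0.55 and Cox4i1 by 0.90 ± 0.23. Their median was 0.52 (camera, adjusted p = 0.000275; adjusted p = 0.478 with an estimated correlation). Of 22 adrenergic and cyclic AMP signalling genes 10 rose and 3 fell (10 and 4 over the list alone; camera, adjusted p = 0.0233; adjusted p = 0.368 with an estimated correlation). Adrb1, the beta-1 adrenergic receptor gene, rose by 1.64 ± 0.24. Of 7 neuronal markers 5 rose and 1 fell (5 and 1 over the list alone; camera, adjusted p = 0.00586; adjusted p = 0.368 with an estimated correlation). The synaptic vesicle genes Syt1 (3.53 ± 0.19) and Slc17a7 (3.20 ± 0.27) were among those that rose. Of 9 thyroid hormone genes 4 rose (4 over the list alone, where 1 fell), Hr by 2.49 ± 0.21 and Klf9 by 0.90 ± 0.16 among them (camera, adjusted p = 0.0461; adjusted p = 0.444 with an estimated correlation). Only 2 of the 17 night-higher genes rose with age, Pde4b and Pde10a (1 over the list alone), at a list median of 1.92 (camera, adjusted p = 0.00263, and adjusted p = 0.550 with an estimated correlation). In this fit a night difference that depends on age adds to the error of these genes. Relative to E21 their median at P40 was -0.312 at mid-day and 4.05 at mid-night. Not passing therefore does not show that they were unchanged.

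Genes of the remaining lists went both ways or in small numbers, and camera did not call these lists. Pineal transcription factors were split, 5 up and 4 down of 14 (the same counts over the list alone). The homeobox genes Pax4 (3.04 ± 0.28) and Lhx4 (2.15 ± 0.31) rose, Lhx9 fell by 3.75 and Pax6 by 0.95. In the circadian clock list 6 of 16 rose and 1 fell (6 and 2 over the list alone), with Nr1d1, a nuclear receptor of the clock, up by 2.25 ± 0.17 and Dbp by 1.34 ± 0.31. Of 15 immediate early genes 4 rose and 1 fell (4 and 1 over the list alone), with Fos up by 2.44 ± 0.30 and Btg2 down by -1.90 ± 0.32. Of 17 cholesterol synthesis genes 7 fell and 1 rose (7 and 1 over the list alone). Among cell-type markers, 5 of 11 for microglia and macrophages rose and 2 fell (6 and 2 over the list alone), C1qa by 1.57 ± 0.17. Astrocyte markers parted, 4 up and 5 down of 9 (the same over the list alone), with Vim at -1.42 ± 0.23 and Slc1a2 at 0.69 ± 0.21. The list median was -0.76 and its mean 0.152. Smooth muscle and pericyte markers fell in 5 of 7 cases (5 over the list alone), Tagln by -1.45 ± 0.33. Mast cell markers fell in 3 of 5 (3 over the list alone, where 1 rose), Cpa3 by -2.08 ± 0.23. Of 5 oligodendrocyte markers 2 rose (2 over the list alone), Ermn by 1.46 ± 0.21. Of 4 Schwann cell markers 1 rose and 1 fell (1 and 1 over the list alone). Of 9 choroid plexus markers 2 rose and 1 fell (2 and 1 over the list alone), Aqp1 by -1.95 ± 0.35.

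**Figure D2:**
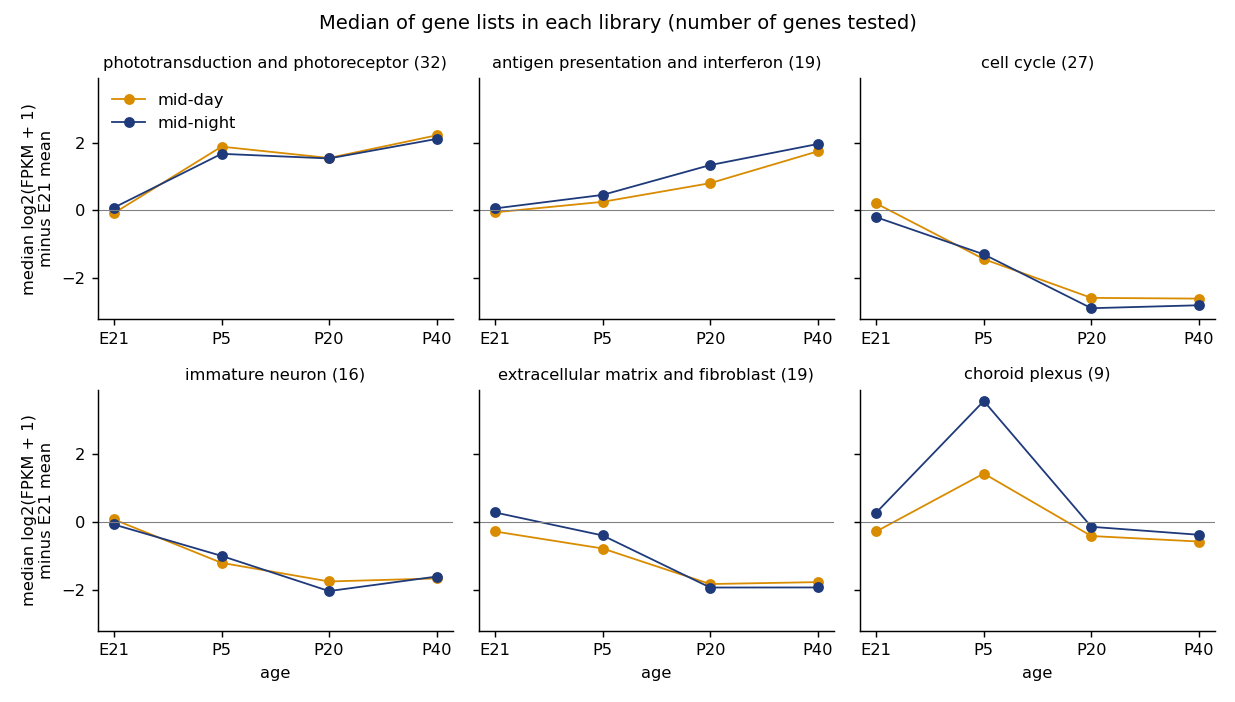
Median over the genes of 6 lists of log2(FPKM + 1) in each library minus the E21 mean, by age, with mid-day in orange, mid-night in blue and the number of genes tested in brackets. The cell cycle, immature neuron and matrix lists lie below 0 at P20 and P40 and the antigen presentation list is highest at P40, while the choroid plexus list peaks in the P5 mid-night library.

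The largest increases between E21 and P40 were in Asmt, the lipoxygenase gene Alox15 (6.16 ± 0.20), the protease inhibitor gene A2m (5.68 ± 0.21), Psap, Scg2 (5.17 ± 0.47) and Car3 (4.88 ± 0.19). They also included Mpp4 (4.83 ± 0.19), Eef1a2 (4.77 ± 0.40), Tuba4a (4.65 ± 0.34) and Lgals3 (4.63 ± 0.28). The largest decreases were in H19, Nnat, Nt5dc2 (-5.18 ± 0.22), Tubb2b, Grm6 (-4.69 ± 0.24), Tpm1, Top2a, Pcp4 (-4.46 ± 0.19), Postn (-4.43 ± 0.18) and the prohormone convertase gene Pcsk2 (-4.23 ± 0.21). The values for Psap (5.53 ± 1.15) and Tpm1 (-4.65 ± 0.22) are uncertain, since each is 1 of several transcripts of its gene that may share reads (4 for Psap and 9 for Tpm1). Psap did not pass without the P40 mid-night library or under robust eBayes (adjusted p = 0.0518 and 0.0714). In all, 1602 transcripts rose and 2674 fell (limma, 4276 of 9960), of which 950 and 1331 did so by at least 2-fold. All transcripts together had a median change of -0.18. After quantile normalization, which removes such a shift, 1957 rose and 2176 fell. Without the P40 mid-day library the count was 2625, and without P40 mid-night 2333.

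The step from E21 to P5 addresses what changes around birth. Between E21 and P5, Asmt rose by 5.94 ± 0.24, Ddc by 2.88 ± 0.30, Gch1 by 2.61 ± 0.27 and Tph1 by 2.52 ± 0.42. These were again 4 of the 8 melatonin genes (4 adjusted over the list alone; camera, adjusted p = 5.94e-05; adjusted p = 0.394 with an estimated correlation). Of the phototransduction genes 21 of 32 rose (29 over the list alone), Gngt2 by 2.52 ± 0.30 and Prph2 by 2.39 ± 0.40 (camera, adjusted p = 1.67e-19; adjusted p = 0.394 with an estimated correlation). The membrane scaffold gene Mpp4 (4.75 ± 0.19), Alox15 (4.59 ± 0.20) and Fcer1a (5.04 ± 1.18), a subunit of the IgE receptor, were with Asmt the largest increases. Neuronal markers rose in 5 of 7 cases (5 over the list alone), Slc17a7 by 3.12 ± 0.27 (camera, adjusted p = 0.00727; adjusted p = 0.394 with an estimated correlation). Cell-cycle genes fell in 24 of 27 cases (25 over the list alone), Top2a by -1.90 ± 0.22 (camera, adjusted p = 9.89e-16; adjusted p = 0.394 with an estimated correlation). Immature neuron genes fell in 11 of 16 (13 over the list alone, where 1 rose), Tubb2b by -1.79 ± 0.17 (camera, adjusted p = 7.85e-06; adjusted p = 0.394 with an estimated correlation). The largest decreases were in Nkain3 (-3.00 ± 0.19), H19 (-2.99 ± 0.27), Pcsk2 (-2.98 ± 0.21) and Grm6 (-2.87 ± 0.24).

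Markers of choroid plexus, the epithelium that makes cerebrospinal fluid, rose between E21 and P5 in 8 of 9 cases (8 adjusted over the list alone), with a median of 2.55 (camera, adjusted p = 8.68e-07; adjusted p = 0.411 with an estimated correlation). Ttr, the thyroxine carrier of that epithelium, stood at 1045 and 1299 FPKM at E21, 2889 FPKM at P5 mid-day and 17323 FPKM at P5 mid-night. The skeletal muscle marker Tnnc2, the only one of its list to be tested, rose by 2.57 ± 0.26 at P5 to 9.83 and 5.31 FPKM. In all, 826 transcripts rose and 681 fell (limma, 1507 of 9960; 898 by at least 2-fold). Which direction held more transcripts depended on the setting: after quantile normalization 919 rose and 993 fell, after median centring 854 and 851, and at a pseudocount of 5 686 and 776. The count was 601 without E21 mid-day, 923 without E21 mid-night, 484 without P5 mid-day and 646 without P5 mid-night. Fcer1a no longer passed without E21 mid-night, P5 mid-day or P5 mid-night (adjusted p = 0.131, 0.224 and 0.0531). Nor did it pass at a pseudocount of 5, with no filter on FPKM, under robust eBayes or without time of day as a term (0.0572, 0.0836, 0.153 and 0.0892). Fcer1a stood at 0.907 and 0.697 FPKM at E21 mid-day and mid-night and at 52.7 and 63.9 FPKM at P5. Its night difference at P20 and P40 adds to the error of this fit, so not passing does not show that it was unchanged.

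From P5 to P20 decreases outnumbered increases. Cell-cycle genes fell again, 21 of 27 (23 adjusted over the list alone), Top2a by -2.62 ± 0.22 and Cdk1 by -2.36 ± 0.24 (camera, adjusted p = 1.92e-15; adjusted p = 0.466 with an estimated correlation). Matrix genes fell in 11 of 19 cases (14 over the list alone, where 1 rose), Postn by -2.46 ± 0.18 and Col1a1 by -1.94 ± 0.31 (camera, adjusted p = 4.90e-07; adjusted p = 0.466 with an estimated correlation). Immature neuron genes fell in 5 of 16 (8 over the list alone), Tubb2b by -2.98 ± 0.17 (camera, adjusted p = 0.000384; adjusted p = 0.466 with an estimated correlation). Antigen presentation genes rose in 6 of 19 cases (10 over the list alone), Cd74 by 1.75 ± 0.27 and Irf7 by 1.21 ± 0.20 (camera, adjusted p = 3.13e-13; adjusted p = 0.466 with an estimated correlation). Choroid plexus markers fell in 7 of 9 (7 over the list alone), Ttr by -3.62 ± 0.62 and Aqp1, a water channel, by -3.02 ± 0.35 (camera, adjusted p = 8.43e-06; adjusted p = 0.466 with an estimated correlation). Tnnc2 fell by -2.86 ± 0.26.

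The largest increases from P5 to P20 were in the G protein regulator gene Rgs7 (3.18 ± 0.21), A2m (2.86 ± 0.21), Dpt (2.85 ± 0.18) and the calcium channel gene Cacna1h (2.68 ± 0.29). The largest decreases were in Mfrp (-4.78 ± 0.49), the serotonin receptor gene Htr2c (-4.50 ± 0.42), Sostdc1 (-4.44 ± 0.51) and Mdk (-3.66 ± 0.26). Like the choroid plexus markers, Mfrp, Htr2c and Sostdc1 were highest at P5 mid-night, at 74.2, 56.4 and 65.7 FPKM, against 18.5, 14.1 and 14.8 FPKM at P5 mid-day. In all, 102 transcripts rose and 597 fell (limma, 699 of 9960), against a median change of all transcripts of -0.18. After quantile normalization 219 rose and 313 fell, and after centring each library on its median 145 and 397. The count was 417 without P5 mid-day, 58 without P5 mid-night, 190 without P20 mid-day and 50 without P20 mid-night. Cacna1h did not pass without P5 mid-night (adjusted p = 0.0573), Mfrp without P20 mid-night (0.0606), and Sostdc1 without P5 mid-night or P20 mid-night (0.0700 and 0.0732).

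Between P20 and P40 no transcript passed (limma, 0 of 9960; 669 at an unadjusted p under 0.05). Of the 19 antigen presentation genes 16 rose when adjusted over the list alone and 0 over all genes. The list as a whole was higher at P40, with a median of 0.71 (camera, adjusted p = 1.35e-17; adjusted p = 0.487 with an estimated correlation). Cd74 averaged 11.9 ± 1.95 FPKM at P20 and 19.9 ± 1.10 FPKM at P40, Irf7 8.21 ± 2.77 and 20.7 ± 1.26 FPKM. Matrix genes had a median of -0.37, 0 of 19 falling over all genes and 1 over the list alone (camera, adjusted p = 8.23e-06; adjusted p = 0.688 with an estimated correlation). Erythroid markers were lower, with a median of -1.02, 0 over all genes and 1 over the list alone (camera, adjusted p = 4.96e-06, and adjusted p = 0.688 with an estimated correlation). Relative to E21 their median was -0.277 at P20 mid-day and -1.315 at P20 mid-night, against -1.821 and -1.397 at P40. The fall was thus mostly against 1 library, P20 mid-day.

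The second question is which transcripts differ between mid-night and mid-day. Averaged over the 4 ages, no transcript passed (limma, 0 of 9960; 1011 at an unadjusted p under 0.05). The 17 genes known as night-higher in the adult gland had a median of 1.74 over the 4 ages, 0 of them passing over all genes and 13 adjusted over the list alone (camera, adjusted p = 3.72e-13; adjusted p = 0.473 with an estimated correlation). In this average an effect that depends on age adds to the error, and Aanat was at 3.32 ± 1.19.

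At P20 and P40 the nocturnal programme of the gland was plain in single genes. Aanat stood at 6.21 FPKM at mid-day and 572 FPKM at mid-night at P20 and at 1.72 and 321 FPKM at P40 (log2 difference 6.60 ± 0.28, adjusted p = 0.000133). Slc15a1, a peptide transporter gene, went from 1.61 to 366 and from 0.216 to 736 FPKM (8.19 ± 0.48) in 1 of its 2 transcripts. Atp7b, a copper transporter gene, went from 1.41 to 124 and from 0.753 to 85.0 FPKM (5.66 ± 0.32). All 17 night-higher genes rose (17 adjusted over the list alone), with a median of 3.41 (camera, adjusted p = 2.17e-37; adjusted p = 0.670 with an estimated correlation). Among them were the deiodinase gene Dio2 (3.41 ± 0.49), the dopamine receptor gene Drd4 (2.96 ± 0.19), Camk1g (2.56 ± 0.26), Gem (2.42 ± 0.42) and Mapk6 (1.08 ± 0.21). In the melatonin list only Aanat and Mat2a (1.96 ± 0.19) rose over all genes (3 up and 1 down over the list alone; camera, adjusted p = 0.00824; adjusted p = 0.826 with an estimated correlation). Tph1 at -0.21 ± 0.52 and Asmt at 0.38 ± 0.25 did not pass.

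Of 15 immediate early genes 6 rose at night (10 up and 1 down adjusted over the list alone), with a median of 0.89 (camera, adjusted p = 4.17e-09; adjusted p = 0.826 with an estimated correlation). The phosphatase gene Dusp1 rose by 4.58 ± 0.32, the orphan receptor gene Nr4a1 by 3.52 ± 0.32 and Egr1 by 1.70 ± 0.17. Fos was at 0.82 (adjusted p = 0.0999). In the clock list 3 of 16 rose, Per1 (2.31 ± 0.27), Per2 (1.68 ± 0.21) and Cry2 (1.89 ± 0.25). Arntl, which encodes the partner of CLOCK, fell by -1.58 ± 0.17 (4 up and 1 down over the list alone; camera, adjusted p = 0.000679; adjusted p = 0.826 with an estimated correlation). Of 22 adrenergic and cyclic AMP genes 5 rose and 1 fell (7 and 1 over the list alone; camera, adjusted p = 0.00104; adjusted p = 0.670 with an estimated correlation). The phosphodiesterase genes Pde10a (3.39 ± 0.29) and Pde4b (2.64 ± 0.21), the transcription factor gene Crem (3.72 ± 0.28) and the alpha-1B adrenergic receptor gene Adra1b (0.93 ± 0.17) were among those that rose. The adenylyl cyclase gene Adcy1 fell by -1.96 ± 0.24. Dusp1, Nr4a1, Per1, Pde10a, Pde4b and Crem are also in the night-higher list. Among pineal transcription factors, Bsx rose by 2.30 ± 0.25 and Isl2 fell by -1.15 ± 0.19. Among phototransduction genes, Pdc fell by -1.83 ± 0.36 and Cabp4 by -1.12 ± 0.24. Of 27 cell-cycle genes 2 rose, Pcna (1.06 ± 0.19) and Kif11 (1.12 ± 0.21), with 2 up and 2 down over the list alone and a list median of -0.03. No member of the matrix, endothelial, astrocyte, microglia, smooth muscle, erythroid or choroid plexus lists passed over all genes.

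**Figure D3:**
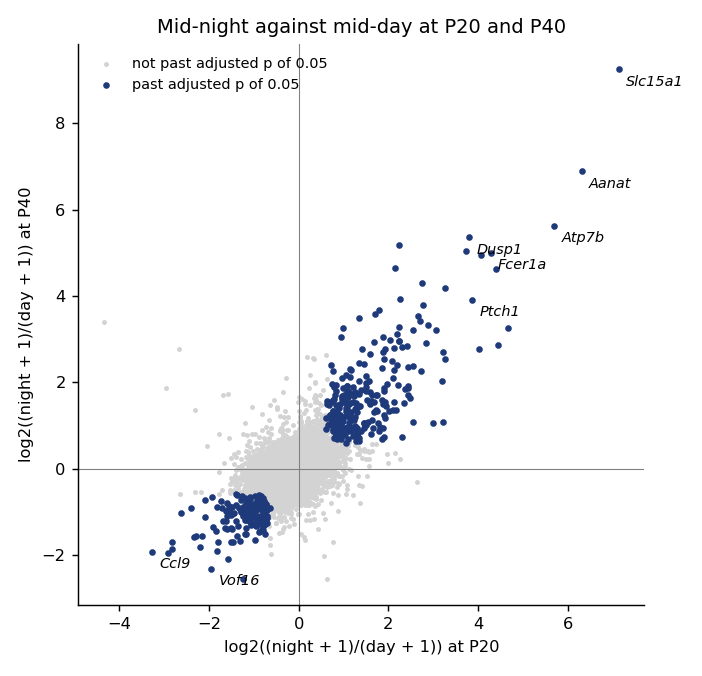
Log2((night + 1)/(day + 1)) of each transcript at P20 (x axis) and at P40 (y axis), with transcripts past an adjusted p of 0.05 in blue and the others in grey. The 2 ages are pairs of separate pools, and across transcripts their night differences correlated at 0.61.

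The 10 largest night increases also included Fcer1a (4.64 ± 0.22), the kinase genes Dclk3 (4.52 ± 0.22) and Sik1 (4.51 ± 0.22), the insulin receptor substrate gene Irs2 (4.38 ± 0.30). Ptch1, the hedgehog receptor gene, was at 7.30 and 121 FPKM at P20 and 7.96 and 133 FPKM at P40 (3.89 ± 0.18). The largest night decreases were in the chemokine gene Ccl9 (-2.60 ± 0.34), the sialyltransferase gene St8sia3 (-2.42 ± 0.24), Hs3st2 (-2.33 ± 0.23), Ndufv3 (-2.25 ± 0.45) and Vof16 (-2.14 ± 0.19). They were followed by Ptpn21 (-2.01 ± 0.18), Adcy1, Ndrg1 (-1.92 ± 0.22), the kinase gene Sgk1 (-1.90 ± 0.28) and Rgs20 (-1.86 ± 0.16). In all, 279 transcripts were higher and 158 lower at mid-night (limma, 437 of 9960), 210 and 90 of them by at least 2-fold. The median of all transcripts was -0.11, and after centring each library on its median 359 were higher and 124 lower. The count was 266 without E21 mid-day, 267 without E21 mid-night, 267 without P5 mid-day, 263 without P5 mid-night. It was 182 and 183 without P20 mid-day and mid-night, 151 and 150 without those of P40, and 105 with no filter on FPKM. Leaving out either library of P20 leaves the P40 pair alone, 1 library for each time, to estimate this night effect, and the reverse. From P40 alone Ccl9 was at -1.92, Adcy1 at -1.58 and Ndufv3 at -1.69. From P20 alone Ndufv3 was at -2.81 and Sgk1 at -1.25. These genes were called over both ages, and a fit with 1 of the ages taken out also has 1 residual degree of freedom fewer. With no filter on FPKM, Ccl9, Ndufv3, Adcy1 and Sgk1 did not pass (0.0883, 0.173, 0.0660 and 0.0982), nor did Ndufv3 at a pseudocount of 0.1 or under robust eBayes (0.0596 and 0.143). Both transcripts of Crem rose (3.72 and 3.96), whereas with the 2 transcripts of Ndufv3 summed it did not pass (-0.48, adjusted p = 0.182).

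Night differences at P20 and P40 resembled each other gene by gene. Of the transcripts at least 2-fold higher at mid-night, 146 were shared by P20 and P40 where 7.39 would be by chance, and 51 of those at least 2-fold lower were shared where 3.62 would be. Another 8 went in opposite directions. Over the 9960 transcripts, which are not independent replicates, the night differences at P20 and P40 correlated at 0.61 (Spearman 0.426). For the other pairs of ages the Pearson values lay between -0.028 and 0.229.

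At the single ages, values without a test, 514 transcripts were at least 2-fold apart at P20 (243 higher at mid-night and 271 lower) and 436 at P40 (303 and 133). Slc15a1, Aanat and Atp7b led at both ages (7.14, 6.31 and 5.70 at P20; 9.24, 6.89 and 5.62 at P40). They were followed at P20 by Crem (4.67), Hhip (4.45) and Dclk3 (4.41), and at P40 by Dusp1 (5.36), the splicing factor gene Zrsr1 (5.18) and Irs2 (5.04). The lowest were Psap (-4.34), Ccl9 (-3.27), St8sia3 (-2.90) and Hs3st2 (-2.81) at P20, and Eef1a1 (-2.56), Sgk1 (-2.55), Vof16 (-2.33) and Depdc7 (-2.09) at P40. Of the 17 night-higher genes, 16 were at least 2-fold higher at mid-night at P20 and 17 at P40, with medians of 3.23 and 4.17, each above all 10000 random lists of matched expression. Erythroid markers were lower at mid-night at P20, with a median of -1.05 and 4 of 7 at least 2-fold lower, and higher at P40 (0.51). Oligodendrocyte markers had medians of -0.88 at P20 and 0 at P40. Higher than most random lists at both ages were immediate early (0.51 and 1.17), clock (0.18 and 0.49) and adrenergic and cyclic AMP genes (0.16 and 0.29). At P20 alone these were antigen presentation (0.36), choroid plexus (0.15) and cell-cycle genes (0.02), and at P40 alone genes of melatonin synthesis (0.52) and thyroid hormone (0.28), with matrix genes lower (-0.32). All transcripts had a median of -0.16 between the P20 libraries. After quantile normalization 302 were at least 2-fold higher and 151 lower at P20, and after median centring 336 and 154. The Psap value is for 1 of 4 transcripts and was -0.31 with these summed. Eef1a1 has near-identical copies elsewhere in the genome, so both are uncertain.

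At P5, 154 transcripts were at least 2-fold higher at mid-night and 30 lower (184 of 9960). Of 9 choroid plexus markers 7 were at least 2-fold higher, with a median of 1.97, above all 10000 random lists of matched expression. Markers of erythroid cells (median 0.60, percentile 100), matrix (0.43, percentile 100) and microglia (0.44, percentile 99.82) and oncofetal genes (0.38, percentile 99.65) and those of oxidative phosphorylation (0.16, percentile 98.03) were also higher in the P5 mid-night library than most random lists. Genes of phototransduction (-0.21, percentile 0) and melatonin synthesis (-0.24, percentile 0.40) and pineal transcription factors (-0.10, percentile 2.37) were lower. Ttr (2.58), Kl (2.08), Sostdc1 (2.08), Kcnj13 (2.07) and Folr1 (1.99) were among the largest increases, with the cilium gene Enkur (3.09 and 15.4 FPKM). Ttr was the highest transcript in both P5 libraries, and quantile normalization therefore set its difference to 0. The 17 night-higher genes had a median of 0.31 at P5 (percentile 99.9 of the random lists), 2 of them at least 2-fold higher. Aanat was at 153 FPKM at mid-day and 225 FPKM at mid-night, and Atp7b at 10.3 and 27.4 FPKM. The lowest values were for Psap (-3.44), Ccdc72 (-2.03), Gngt1 (-2.03) and Churc1 (-1.40); with its 4 transcripts summed, Psap was at 0.50.

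At E21, 78 transcripts were at least 2-fold higher at mid-night and 124 lower (202 of 9960). Hnrpd (4.23 and 3.18 for 2 transcripts), Gngt1 (3.60), Rpl34 (3.35), Rpl22l1 (3.35) and Ins1 (3.10) were highest. Rpl23 (-3.44), Ccdc72 (-3.43), Atp5i (-3.30) and Rpl37a (-3.19) were lowest. With the 4 transcripts of Hnrpd summed its difference was -0.77, so these values are uncertain, as are those of the ribosomal protein genes, which have near-identical copies. None of the 17 night-higher genes was 2-fold apart (0 higher and 0 lower; median -0.07), and Aanat was at 13.5 FPKM at mid-day and 9.45 FPKM at mid-night. Markers of matrix and of endothelium were higher in the E21 mid-night library (medians of 0.56 and 0.38, percentiles 100 and 99.98 of random lists), as were those of choroid plexus (0.56, percentile 100) and of smooth muscle and pericytes (0.28, percentile 99.03). So were immediate early genes (0.23, percentile 99.78) and genes of phototransduction (0.16, percentile 99.82). Cell-cycle genes were lower (-0.41, percentile 0).

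**Figure D4:**
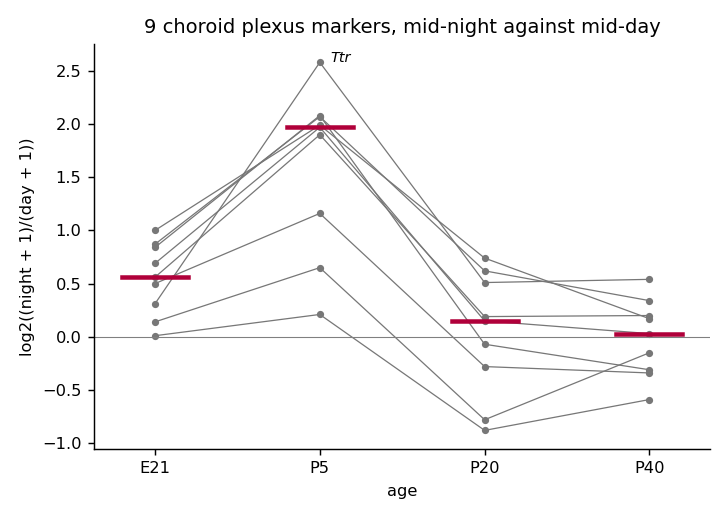
Log2((night + 1)/(day + 1)) of 9 choroid plexus markers at each age (grey points and lines, 1 per gene) with their median (red bars). The medians were 0.56 at E21, 1.97 at P5, 0.15 at P20 and 0.03 at P40.

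Over E21 and P5 together 3 transcripts differed between mid-night and mid-day (limma, 3 of 9960; 566 at an unadjusted p under 0.05): Enpp2 (1.90 ± 0.18) and Sostdc1 (2.07 ± 0.21) were higher and Alg3 lower (-1.71 ± 0.18), each with an adjusted p of 0.0478. These 3 fall outside the rule for named genes and were picked after their values were seen. Alg3 was listed at 0 in 6 of the libraries and is 1 of 2 transcripts of its gene. Like the choroid plexus markers, Enpp2 and Sostdc1 were highest at P5 mid-night, at 497 and 65.7 FPKM, against 129.5 and 14.8 FPKM at P5 mid-day. Whether that pool held choroid plexus tissue is left open below, so it is open whether their difference belongs to the gland. Choroid plexus markers had a median of 1.33, 0 of 9 passing over all genes and 6 adjusted over the list alone (camera, adjusted p = 2.69e-11; adjusted p = 0.910 with an estimated correlation). Matrix (0.43; camera, adjusted p = 3.02e-09; adjusted p = 0.851 with an estimated correlation) and endothelial markers (0.28; camera, adjusted p = 0.000637; adjusted p = 0.851 with an estimated correlation) were higher too, again with 0 members past the test over all genes. The 17 night-higher genes had a median of 0.06 (camera, adjusted p = 0.836). The count was 0 without any 1 of the E21 mid-day, E21 mid-night, P5 mid-day or P5 mid-night libraries, after median centring, and at a pseudocount of 5.

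Whether the night difference itself changed between the 2 younger and the 2 older ages was tested with an interaction term. Of the 17 night-higher genes, 13 had a larger night increase at P20 and P40 than at E21 and P5 (17 adjusted over the list alone), with a median difference of 3.35 (camera, adjusted p = 5.69e-41; adjusted p = 0.590 with an estimated correlation). The 10 transcripts with the lowest p were Aanat (6.56 ± 0.39), Fcer1a (4.59 ± 0.31), Sik1 (4.57 ± 0.32), Ptch1 (3.70 ± 0.26), Dclk3 (4.14 ± 0.31), Irak2 (2.72 ± 0.23), Ribc2 (3.10 ± 0.26), Atp7b (5.09 ± 0.45), Slc15a1 (7.53 ± 0.67) and Drd4 (3.04 ± 0.27). Drd4 had reached 32.1 FPKM at mid-day and 26.7 FPKM at mid-night at P5, whereas at P20 it was at 2.79 and 34.4 FPKM. Slc15a1 was listed at 0 in both E21 libraries and at P5 mid-day. The immediate early genes Dusp1 (4.46 ± 0.46), Nr4a1 (3.58 ± 0.45) and Egr1 (1.86 ± 0.25) and the phosphodiesterase genes Pde4b (2.45 ± 0.30) and Pde10a (3.17 ± 0.41) were also called, as were Mat2a (2.09 ± 0.27), Bsx (2.49 ± 0.35) and, with the opposite sign, Arntl (-1.54 ± 0.24). Choroid plexus and matrix markers moved the other way, with medians of -1.03 and -0.61. None of their members passed over all genes (0 of 9 and 0 of 19), against 8 and 7 over the lists alone (camera, adjusted p = 0.000105 and 3.96e-05; adjusted p = 0.591 for both with an estimated correlation).

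In all, 61 transcripts had a more positive and 14 a more negative night difference at the older ages (limma, 75 of 9960), where the median of all transcripts was -0.14. The count was 6 without E21 mid-day, 6 without E21 mid-night, 9 without P5 mid-day, 9 without P5 mid-night, 29 without P40 mid-day and 28 without P40 mid-night. With no filter on FPKM it was 0, and none of the 10 transcripts passed (adjusted p from 0.0987 to 0.218). With the night effect of P5, P20 and P40 set against that of E21 it was also 0, and again none of the 10 passed (0.797 to 0.928; Aanat 0.914). That coding fits 1 night effect to P5, P20 and P40, so a night difference that sets P5 apart from P20 and P40 adds to its error. Aanat was still at 5.06 there, and not passing does not show that the night effects were alike. Leaving out either library of an age takes that age out of the night effects, so leaving out P5 mid-day, P5 mid-night or both gives the same estimate. Without P5 the differences were 2.77 for Irak2, 3.13 for Ribc2, 8.19 for Slc15a1 and 2.86 for Drd4. Without E21 they were 2.68, 3.06, 6.87 and 3.22, and 4.56 for Sik1. Each of these lies within the SE of the estimate from all libraries given above. A call lost in these fits does not show that it rests on the age left out, since they have 1 residual degree of freedom fewer. Slc15a1 did not pass at a pseudocount of 0.1 or under robust eBayes (0.0741 and 0.111), nor Drd4 at a pseudocount of 5 (0.0542). With a linear trend of the night effect over age, Irak2 (0.0638) and Drd4 did not pass.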

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

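The tests of choroid plexus tissue and of scaling for the P5 mid-night library, and that of single choroid plexus markers at P40, were chosen only after the result was seen.

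Night effects that differ between the older and the younger ages, by a test of the difference itself, are the results collected here. For single transcripts the difference (log2, P20 and P40 minus E21 and P5) was 6.56 for Aanat, 4.59 for Fcer1a, 4.57 for Sik1, 3.70 for Ptch1, 4.14 for Dclk3, 2.72 for Irak2, 3.10 for Ribc2, 5.09 for Atp7b, 7.53 for Slc15a1 and 3.04 for Drd4. For lists the median difference was 3.35 for night-higher genes, 0.74 for immediate early genes, 0.27 for the clock, 0.23 for adrenergic and cyclic AMP signalling, 0.11 for melatonin synthesis and 0.07 for the cell cycle (adjusted p = 0.0492), where the median of all transcripts was -0.14. It was -1.03 for choroid plexus, -0.61 for matrix and -0.50 for endothelial markers. Members that passed over all genes were 13 of 17 night-higher genes, 3 of 15 immediate early, 3 of 22 adrenergic and cyclic AMP and 2 of 8 melatonin genes, all higher, and 1 of 16 clock genes, lower. The adrenergic and cyclic AMP and melatonin genes that passed are also night-higher genes, as are Dusp1 and Nr4a1 among the immediate early ones. These lists are therefore not separate support. None passed of 27 cell-cycle, 9 choroid plexus, 19 matrix and 9 endothelial genes. Over the list alone, 8 choroid plexus and 7 matrix genes passed as lower and no endothelial ones, against 17 night-higher, 2 melatonin and 2 cell-cycle genes as higher. Immediate early genes then passed as 6 higher and 1 lower, adrenergic and cyclic AMP genes as 5 and 1, and clock genes as 3 and 1. These list calls were made with camera at a preset correlation, and none passed with an estimated one.

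In the night effect at P20 and P40, scaling of the libraries is argued against: after quantile normalization 87.6% of the 437 called transcripts were still called in the same direction. With mid-day and mid-night exchanged at P40 alone, 0 transcripts were called against 437, which argues against differences between pools that are unrelated to time of day. Among 10 marker lists of other cell types the largest absolute median over both ages was -0.32, for smooth muscle and pericytes, which argues against a share of these cell types that differs alike at night at P20 and P40. This average hides opposite values at the single ages, such as erythroid markers at -1.05 at P20 and 0.51 at P40 and oligodendrocyte markers at -0.88 at P20 and 0 at P40, so a different share of these cells at P20 alone stays open. A response of the gland to time of day is a hypothesis beside it, and anything else shared by both mid-night collections, such as handling in the dark, may add to the effect and was not tested.

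In the P5 mid-night library, the 8 choroid plexus markers other than Ttr had a median of 1.93 above mid-day, 7 of them over 1.5-fold and the lowest at 0.21. These are the genes that show the pattern, so whether that pool held choroid plexus tissue is left open. In the same library phototransduction (-0.207), melatonin synthesis (-0.243) and pineal transcription factor genes (-0.104) had lower medians than at mid-day, night-higher genes a higher one (0.309). A share of other tissue would lower genes of the gland, but so would a night decrease at P5, so these values do not decide it. Scaling or depth is argued against by the median of all transcripts at P5, 0.073. Time of day acting on these genes at every age is argued against by their medians of 0.04 at P20 and -0.06 at P40. At P40, 6 of the markers reached 1 FPKM in both libraries and none of them was more than 0.34 higher. Their median at E21 was 0.62, which does not argue against an effect at that age. Ttr, the most abundant, stood at 2889 and 17323 FPKM at P5. It was higher at mid-night at every age, by 0.31 at E21, 2.58 at P5, 0.51 at P20 and 0.54 at P40, so the argument against time of day does not cover Ttr. Choroid plexus tissue and a night increase of these genes at P5, or at E21 and P5, cannot be told apart with 1 pool for each time.

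At E21, transcripts spanning under 2 kb (367 tested) had a median absolute difference between the libraries of 0.292, at percentile 100 of random sets of longer transcripts of like expression (whose upper bound was 0.208), which is consistent with unstable values of short transcripts. Such an excess was also present at P5, P20 and P40 (percentiles 100, 99.82 and 100). Without these transcripts 159 of the 202 at E21 were still 2-fold apart, so those of short span account for a minor part of that count. Span was taken on the genome with introns, so short transcripts of genes with introns can lie outside this group. How much such transcripts add was not tested. Transcripts of symbols with several transcripts made up 21.3% of those 2-fold apart and 4.7% of those tested (one-sided Fisher's exact test, p = 2.44e-17). Transcripts of the same gene are not independent, so this p can overstate the excess. Reads split between them likely add to the count of 202. The 17 night-higher genes did not show an adult night difference at E21, with a median of -0.07 against 4.17 at P40. For the transcripts 2-fold apart at E21, time of day acting as in the adult gland is left undecided. Of these, 57.9% had the same sign at P40 (exact 95% interval 50.8 to 64.8%, over transcripts that are not independent).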

How the results depend on the processing

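The tests without both P5 libraries and without transcripts under 2 kb were chosen only after the data were seen. Every other alternative was planned.

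With a pseudocount of 0.1, 1 transcript changed between P20 and P40, and those at least 2-fold apart between mid-night and mid-day numbered 456 at E21, 407 at P5, 1096 at P20 and 849 at P40. With a pseudocount of 5 these were 91, 59, 181 and 192, P20 against P5 gave 397, night at E21 and P5 0, and the difference of night effects 37. A larger pseudocount shrinks differences of low transcripts by construction. With no filter on FPKM, P20 against P5 gave 373, night at P20 and P40 105, night at E21 and P5 0 and the difference of night effects 0. With at least 5 FPKM in 2 libraries, 2322 changed with age, 2838 between P40 and E21, 372 between P20 and P5 and 0 at night at E21 and P5, and 91 were 2-fold apart at P5; fewer transcripts are then tested. Night at E21 and P5 gave 1 after quantile normalization, 0 after median centring and 1 without trend. Requiring a 2-fold change as well left 2281 for P40 against E21 and 898 for P5 against E21. The difference of night effects taken as P5, P20 and P40 against E21 gave 0. This coding puts a night difference between P5 and the 2 older ages into the error. A limit of 1.5-fold gave 778, 732, 1909 and 1367 at E21, P5, P20 and P40, and a limit of 3-fold 72, 47, 144 and 157. Without both P5 libraries, night at P20 and P40 gave 266 and the difference of night effects 9, with fewer libraries to estimate the spread. Without transcripts under 2 kb, night at E21 and P5 gave 5. With transcripts summed per symbol, the 2 named transcripts of Hnrpd reversed at E21 to -0.766 and Psap reversed at P5 to 0.503. Reads divided among transcripts of the same gene may account for this, which was not tested. Where no reason is given, the cause was not tested.

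Leaving out 1 library at a time gave 2369 to 3347 for change with age, 2333 to 4253 for P40 against E21, 484 to 1422 for P5 against E21 and 50 to 725 for P20 against P5. For night at P20 and P40 it gave 150 to 267, for night at E21 and P5 0 to 2 and for the difference of night effects 6 to 64. Each fit then has 1 residual degree of freedom fewer, and leaving out either library of an age takes that age out of the night effects. The counts were lowest without E21 mid-day for change with age, P40 mid-night for P40 against E21, P5 mid-day for P5 against E21, P20 mid-night for P20 against P5 and P40 mid-night for night at P20 and P40. Night over the 4 ages stayed at 0 in every alternative run, with 1011 at an unadjusted p under 0.05 in limma.

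For named genes, 492 of the values with a library left out kept their direction and their side of the threshold, and 36 kept the direction but no longer passed. Under the other alternatives these numbers were 1059 and 41, with 2 that moved and 3 that reversed. Of the list results, which include lists that camera did not call, 124 kept their side of the threshold with an estimated correlation and 76 did not. No list call quoted above passed with an estimated correlation, so 124 is not a number of list calls that held. Low depth limits the values of transcripts under 1 FPKM, most of all in the P20 mid-day library.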

Other observations

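The hedgehog pathway genes and the separate transcripts of Slc15a1 and Crem were chosen after their values were seen. The tests of levels from P5 to P20 and of other splits were set after the data were examined but before their own values were computed.

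Beside Ptch1 (log2 night difference at P20 and P40 3.89), the hedgehog-interacting protein gene Hhip was higher at mid-night (3.65, adjusted p = 0.00449 in limma). At P20 it was at 1.49 FPKM at mid-day and 53.5 FPKM at mid-night, and at P40 at 0.906 and 12.8 FPKM. Its night effect differed from that at E21 and P5 by 3.72 (adjusted p = 0.0491). Gli2 was higher by 0.99 (adjusted p = 0.0244). Gli3 at 0.05 and Smo at 0.04 did not pass (adjusted p = 0.916 and 0.946). Gli1, Shh, Ihh and Dhh did not exceed 0.415 FPKM in any library.

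The night increase of Slc15a1 was in a transcript that spans 2442 bp of chromosome 15 (106550095 to 106552536, rn4), at 366 FPKM at P20 mid-night and 736 FPKM at P40 mid-night. The transcript that spans 42500 bp from the same start did not exceed 0.201 FPKM in any library. The 2 transcripts of Crem on chromosome 17 span 67039 and 13796 bp, and both were higher at mid-night (3.72 and 3.96).

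The 256 transcripts at least 2-fold higher at mid-night at P40, with at least 5 FPKM in the higher P40 library, and followed from P5 to P20 may gain their night level or lose their day level in this interval. Their mid-night level rose by a median of 0.61, at percentile 100 of matched random sets (upper bound -0.21), as a gain of the mid-night level requires. The limit of 5 FPKM in the higher P40 library, here mid-night, favours transcripts with a high mid-night level. Their mid-day level had a median of -0.29, at percentile 0 of random sets (lower bound -0.1). This lies between the bounds set for a loss of the mid-day level and leaves it open for the 256 together. For the 17 night-higher genes the median relative to E21 fell at mid-day, from 1.261 at P5 to -0.109 at P20. At mid-night it rose from 1.321 to 3.488.

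For mid-night against mid-day over the 4 ages the real split called 0 transcripts, so that all 32 of the 32 splits of the 8 libraries with age in the fit reach this number by construction, and the comparison decides nothing about chance. The highest other split called 554. It parts P20 and P40 by time of day and keeps both libraries of E21 and of P5 together, where age absorbs them. It is thus the night contrast at P20 and P40 tested above, with no night effect for E21 and P5, and adds no separate support. The 2 splits of this kind, each with 554, are the same fit with the sign reversed. The others called 0 transcripts, the 8 that part every age included.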
